A study of Arabidopsis thaliana with 9 samples.

How the data were processed

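Total RNA from a cell suspension culture of Arabidopsis thaliana was measured on 9 Affymetrix ATH1 arrays, a design that hybridises biotin-labelled RNA to short oligonucleotide probes near the 3 prime ends of transcripts. The labels give 3 groups of 3 biological replicates each. Control cells stayed in 50 microE/m2/s, dark cells spent 1 h without light, and high light cells received 1800 microE/m2/s for 30 min. The labels call the replicates biological, and no label says whether they came from separate cultures, so p-values measure the spread between these samples.

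The deposited values are taken as log2 expression per probe set, computed with RMA in the affy package, per the submitters' processing notes, which give no version and no settings. RMA corrects the background, normalises the quantiles between arrays and summarises the probes of a set. The base of the logarithm is not given in the sources used here and was taken from the range and the nearly equal quartiles of the columns. Quantile normalisation would hide a change that moved most transcripts in 1 direction. RMA values can also be compressed near the floor of the scale. The probe-level scans were not used here, so probe sets were not tested for signal above background. The number of arrays limits the precision.

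The table holds 22810 probe sets. The 64 Affymetrix control sets were kept for quality values, and the other 22746 were tested. Gene names came from the platform annotation given with the data. It lists exactly 1 gene for 13513 probe sets, several for 503 and none for 8730, which are unnamed here. Of the 13513, 13436 were matched to the gene table by gene identifier. Among the 13513, the name is the locus for 11933. Nothing was named from a probe set with several genes.

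Each comparison was fitted with limma 3.58.1 in R 4.3.3, using lmFit with a mean per group over all 9 arrays and eBayes with a constant prior, 6 residual and 2.55 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg within each comparison, and a probe set was called at an adjusted p under 0.05. The moderated F test over the 3 groups used the same fit. In a simulation of high light against control over 22746 probe sets, with 50 sets changed at each size, 26% were called at a log2 change of 0.5, 92% at 1 and 100% at 2 and at 4. The same simulation called 10 unchanged probe sets in high light against control, 0 in dark against control and 15 in high light against dark. The simulated arrays were drawn independently of each other, and large changes stood beside the small ones, which eases the adjusted threshold. These shares may therefore not hold for a comparison with few changed genes.

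The groups, tests, alternatives, naming rule and 27 gene lists were fixed before the data were examined. The lists hold 396 distinct loci, of which the gene table paired 383 with the listed symbol, and 56 had a named probe set. A gene with several probe sets is represented by the one with the highest mean. The lists of plastid and mitochondrial genes were made by rule. That rule was written for locus prefixes and was applied through the chromosome in the gene table. A further 22 lists of gene families were added after the gene table had been seen and before any fold change was computed. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation.

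The naming rule covers, per comparison, the 10 highest and 10 lowest called probe sets with 1 gene and no overlap between the groups. It also covers up to 4 called members of each list, and up to 2 members of a list with none called. Not every list member it covers is named. ELIP1, ELIP2, APX2, HSP101, BAP1, ASN1 and SEN1 belong to the rule but have no named probe set and were not analysed here. Lists for photoprotection, jasmonate, xylem cells and embryo and seed had 0 measured members.

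Alternatives changed 1 choice at a time, except that the intensity trend and robust estimation were changed together. They covered median centring, quantile normalisation, filters on low means, an intensity trend with robust estimation, array weights, the replicate number as a block, probe sets with shared probes, each array left out, only the arrays of both groups, a stricter threshold and other list tests. An RNA quality covariate and lists by locus alone were chosen after seeing the data. The covariate was the mean 3 prime minus 5 prime difference of the actin, GAPDH and ubiquitin control sets. Shared control arrays were simulated with 1000 draws of unchanged groups, and shared high light arrays with 100. Whether the replicate numbers in the labels pair the arrays was checked by the correlation of their deviations from the group means. All 3 same-numbered pairs of high light and control arrays were over 0.1 (0.261 to 0.515), and 2 of 3 pairs were in dark against control (0.0124 to 0.632) and in high light against dark (-0.0336 to 0.485).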

Results

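Transcript levels were compared in cultured Arabidopsis cells kept at 50 microE/m2/s (control), placed in the dark for 1 h, or exposed to 1800 microE/m2/s for 30 min (high light), with 3 arrays per group. The median log2 signal of the arrays lay between 5.55 and 5.67. On the first principal component, which held 47.4% of the variance, high light replicates 2 and 3 had scores of 41.5 and 45.4, and the other arrays had scores from -28.5 to 4.32. High light replicate 1 had the score of 4.32. The 3 prime minus 5 prime log2 difference of the control transcripts, a sign of RNA quality, was 0.93 ± 0.19 in control, 1.02 ± 0.25 in dark and 1.00 ± 0.05 in high light (SD, n = 3). Exact two-sided permutation tests of this index gave p = 0.8 for dark and 0.8 for high light against control and 0.9 between dark and high light, where 3 against 3 arrays cannot go below 0.1. These tests compare groups only, and within control and within dark the index rose with the replicate number.

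The first comparison asked which transcripts differed between high light and the control light. AT5G52050, which encodes a MATE-family transporter, rose from 5.15 ± 0.36 to 9.74 ± 0.56 on the log2 scale (SD, n = 3), a 24.0-fold increase with a limma adjusted p of 0.00045. PUB22, a U-box ubiquitin ligase, rose 15.4-fold (log2 change 3.94, SE 0.46, adjusted p = 0.0082). AT5G52020 and AT1G77640, which encode AP2/ERF-type transcription factors, rose by 3.84 (SE 0.34) and 3.23 (SE 0.21). AT2G22880, a VQ-motif protein gene, rose by 3.35 (SE 0.28) and AT5G48540, a gene for a secreted cysteine-rich repeat protein, by 3.69 (SE 0.47). AT4G27654 and AT3G02840 rose by 4.11 (SE 0.21) and 3.96 (SE 0.22). All of these had adjusted p between 0.00043 and 0.0129. The 3 highest arrays of each of these genes were the high light arrays.

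Among the rapid stress transcription factors, of which 4 of 20 listed were measured, 3 of 4 measured members rose and 0 fell over all probe sets, and 4 rose when adjusted over the list alone. WRKY53, a senescence and defence regulator, rose 10.4-fold (log2 change 3.38, SE 0.41, adjusted p = 0.0092). STZ, the zinc finger repressor also called ZAT10, rose 8.35-fold (3.06, SE 0.42, adjusted p = 0.0174), and WRKY22 rose 6.22-fold (2.64, SE 0.40, adjusted p = 0.0323). The list moved up (median log2 change 2.85, camera adjusted p = 3.9e-10) and kept its call with an adjusted p of 0.0406 with an estimated correlation. The calcium and touch list had 1 of 3 measured members called, and 2 rose when adjusted over the list alone. CML37, a calmodulin-like calcium sensor, rose by 3.27 on the log2 scale (SE 0.36, adjusted p = 0.0067), from a control mean of 4.03 that lay below the lower quartile of every array (4.05 to 4.12) and was not tested against background. This list passed with a camera adjusted p of 0.00015, and of 0.0406 with an estimated correlation. Among markers of singlet oxygen, the excited oxygen formed in illuminated chloroplasts, STZ was the 1 of 4 members called, and 3 rose when adjusted over the list alone (camera adjusted p = 4.6e-06, adjusted p = 0.0604 with an estimated correlation). STZ belongs to both this list and the list of transcription factors.

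Fewer transcripts fell in high light. GI, the clock and flowering regulator GIGANTEA and the 1 measured gene of the circadian clock list, fell to 0.434 of control (log2 change -1.20, SE 0.13, adjusted p = 0.0061). LHCB4.2, an antenna protein of photosystem II, fell to 0.444 of control (-1.17, SE 0.18, adjusted p = 0.0309). XERICO, a RING-type regulator of abscisate levels, changed by -1.05 (SE 0.15, adjusted p = 0.0246), and AT3G49790 by -0.74 (SE 0.08, adjusted p = 0.0064). The dark and high light means were nearly the same for LHCB4.2 (6.39 and 6.30) and for AT3G49790 (5.91 and 5.94). For these genes the arrays do not set high light apart from dark. LHCB4.2 was the 1 of 9 measured photosystem and Calvin cycle genes that passed, and 4 fell when adjusted over the list alone. The list moved down with a median log2 change of -0.31 (camera adjusted p = 1.8e-05), a call lost at an adjusted p of 0.237 with an estimated correlation. The dark and sugar starvation list had 0 of 4 members called by limma, 2 of them lower at an unadjusted p under 0.05, and a median of -0.46 (camera adjusted p = 0.0056, adjusted p = 0.291 with an estimated correlation). Without control replicate 3 that list's adjusted p was 0.0643. In chlorophyll synthesis, CHLM and PORB had log2 changes of -0.60 (SE 0.15) and -0.49 (SE 0.16); 0 of 3 members passed over all probe sets, 2 were lower at an unadjusted p under 0.05, 2 fell when adjusted over the list alone, and the list had a camera adjusted p of 0.0982.

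In total limma called 114 of 22746 probe sets, 100 higher and 14 lower in high light, and 104 of them with an absolute log2 change of at least 1 (94 higher, 10 lower). Of the 55 called sets with 1 named gene, 51 were higher and 4 lower. At an unadjusted p under 0.05 there were 2000 (8.79%, against 5% by chance), and in 2539 (11.2%, against 10% by chance) the 3 arrays of 1 group did not overlap those of the other. With array weights limma called 387 (281 higher, 106 lower), and with the replicate number as a block, which pairs these arrays, 302 (231 higher, 71 lower), 113 of them shared with the 114. The count was 575 without high light replicate 1, 43 and 58 without high light replicate 2 or 3, and 64 and 61 without control replicate 1 or 3. AT5G48540, LHCB4.2, STZ, WRKY22, WRKY53 and XERICO lost their calls without high light replicate 2 (adjusted p 0.0710 to 0.194) and without replicate 3 (0.0536 to 0.172); AT5G48540, WRKY22 and XERICO, with STZ or LHCB4.2 or both, also lost them without control replicate 1 (0.0605 to 0.128), 2 (0.0545 to 0.0954) or 3 (0.0517 to 0.139), and LHCB4.2, WRKY22 and XERICO without dark replicate 1 (0.0528 to 0.0732). With only the 6 arrays of both groups, AT5G48540, LHCB4.2, WRKY22 and XERICO missed the threshold (0.0666 to 0.0770), as LHCB4.2 did after quantile normalisation (0.0515).

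**Figure D1:**
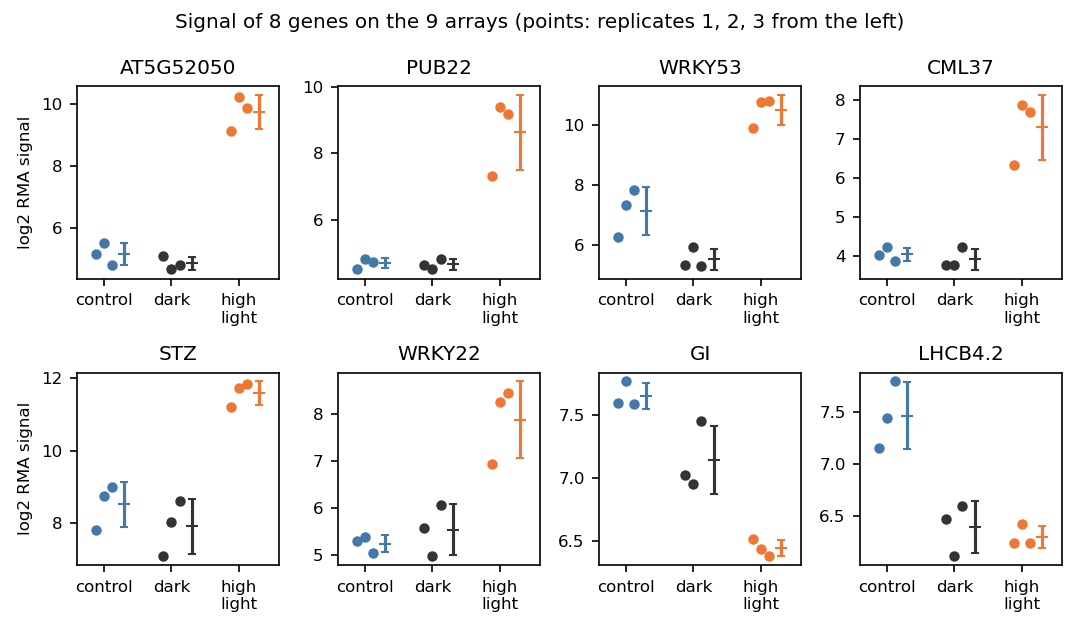
Log2 RMA signal of 8 genes on each of the 9 arrays, with points for replicates 1, 2 and 3 from left to right and a bar for the mean ± SD of each group (n = 3). The 3 high light arrays lie above all control and dark arrays for AT5G52050, PUB22, WRKY53, CML37, STZ and WRKY22, high light replicate 1 being the lowest of the 3. They lie below all control arrays for GI and LHCB4.2. For LHCB4.2 they overlap the dark arrays.

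The second comparison asked what 1 h of darkness changed relative to the control light. No single transcript passed the threshold. LHCB4.2 had the signal 7.47 ± 0.32 in control and 6.39 ± 0.25 in dark (SD, n = 3), a log2 change of -1.08 (SE 0.18) with a limma adjusted p of 0.502. WRKY53 had a log2 change of -1.62 (SE 0.41) and GI one of -0.51 (SE 0.13), both with an adjusted p of 1. AT3G49790 (-0.77, SE 0.08) and AT1G58420 (-1.18, SE 0.14), both chosen after their values were seen, shared the smallest adjusted p of 0.123. The dark arrays were not alike for every gene that rose in high light. CML38, also chosen after its values were seen, had signals of 5.94, 6.20 and 9.50 on dark replicates 1, 2 and 3. Its means were 6.73 in control and 9.79 in high light.

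As a list, the nuclear photosystem and Calvin cycle genes lay lower in the dark: 0 of 9 passed over all probe sets, 3 fell when adjusted over the list alone, and the median log2 change was -0.23 (camera adjusted p = 1.1e-05, lost at an adjusted p = 0.518 with an estimated correlation). PSAN, a subunit of photosystem I, had a log2 change of -0.53 (SE 0.14). The 69 measured genes of the plastid genome, which encodes core photosynthesis and ribosome proteins, had a median of -0.13 (camera adjusted p = 0.0034, lost at an adjusted p = 0.518 with an estimated correlation), with 0 called by limma and 2 lower at an unadjusted p under 0.05. The 4 measured genes of the dark and sugar starvation list had a median of -0.31 (camera adjusted p = 0.0073, lost at an adjusted p = 0.518 with an estimated correlation), with 0 called and 0 at an unadjusted p under 0.05. ATG8E, an autophagy gene, had the value -0.49 (SE 0.31) and AKINBETA1, a kinase subunit gene, -0.40 (SE 0.26). Without control replicate 3 the plastid and starvation lists both had an adjusted p of 0.517, without dark replicate 1 they had 0.537 and 0.0730, and with array weights both had 0.189.

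Limma called 0 of 22746 probe sets between dark and control, and 629 (2.77%, against 5% by chance) had an unadjusted p under 0.05. The 3 arrays of each group did not overlap in 1442 (6.34%, against 10% by chance). Same-numbered arrays deviated together in 2 of 3 pairs here (0.0124 to 0.632), and a fit without pairing can then overstate the error. Shares below chance are therefore no added evidence that darkness changed nothing. The replicate number as a block also gave 0 calls. With array weights, limma called 5, of which 1 was higher and 4 were lower in the dark.

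The third comparison set high light against dark. WRKY53 rose 31.9-fold, from 5.51 ± 0.35 to 10.51 ± 0.51 on the log2 scale (SD, n = 3), with an SE of the log2 change of 0.41 and a limma adjusted p of 0.0011. AT5G52050 rose 29.7-fold (4.89, SE 0.28, adjusted p = 0.00020), PUB22 15.8-fold (3.98, SE 0.46) and AT5G52020 16.5-fold (4.04, SE 0.34). AT2G32030, an acetyltransferase-family gene, rose by 3.86 (SE 0.61), AT4G36500 by 4.17 (SE 0.60), AT4G29780 by 4.05 (SE 0.54) and AT4G27652 by 3.98 (SE 0.34). AT4G27654 rose by 4.30 (SE 0.21) and AT3G02840 by 4.07 (SE 0.22). XERICO had the 1 named decrease (log2 change -0.98, SE 0.15, adjusted p = 0.0257), and GI, at -0.70 (SE 0.13), had an adjusted p of 0.0556.

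The same 3 of 4 rapid stress transcription factors rose, STZ by 3.67 (SE 0.42) and WRKY22 by 2.34 (SE 0.40) besides WRKY53, and 4 rose when adjusted over the list alone. In the calcium and touch list CML37 rose by 3.39 on the log2 scale (SE 0.36, adjusted p = 0.0035) from a dark mean of 3.90, also below the lower quartile of every array, and 1 of 3 members passed over all probe sets and 2 when adjusted over the list alone. In the singlet oxygen list STZ was the 1 of 4 members called, and 4 rose when adjusted over the list alone. These lists had camera adjusted p of 9.1e-11, 0.00046 and 3.7e-08, and each had an adjusted p of 0.0338 with an estimated correlation. The plastid genes (69 measured, median 0.12) and the mitochondrial genes (11 measured, median 0.17) lay higher in high light with a camera adjusted p of 0.0159 each, lost at an adjusted p of 0.521 with an estimated correlation. In these lists limma called 0 genes; 0 plastid genes were higher and 1 lower at an unadjusted p under 0.05, and 1 mitochondrial gene was higher. The plastid call was lost without dark replicate 1 (adjusted p = 0.507), high light replicate 2 (0.367) or high light replicate 3 (0.0762), and the mitochondrial call without dark replicate 3 (0.187) or high light replicate 1 (0.662). The mitochondrial call was also lost without probe sets with shared probes (adjusted p = 0.311), with a filter above the median mean (0.180) and with array weights (0.398). Against control the plastid genes had a median of 0.01 and a mean of -0.05 in high light, which differ in sign, with a camera adjusted p of 0.906. In that comparison 0 plastid genes were higher and 5 lower, and 2 mitochondrial genes were higher and 0 lower, at an unadjusted p under 0.05.

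Limma called 204 of 22746 probe sets, 201 higher and 3 lower in high light than in dark; 176 of the higher and 1 of the lower had an absolute log2 change of at least 1, and 108 had 1 named gene (107 higher, 1 lower). At an unadjusted p under 0.05 there were 1821, and 2336 (10.3%, against 10% by chance) had arrays that did not overlap. Without high light replicate 1 the count was 675, without high light replicate 2 or 3 it was 76 or 84, and without dark replicate 1 or 2 it was 90 or 85. A fit of only the 6 arrays of both groups called 131, and one with array weights 642 (551 higher, 91 lower). With the replicate number as a block, limma called 430 (402 higher, 28 lower), though not all pairs of these arrays deviated together. AT2G32030, AT4G29780, AT4G36500, WRKY22 and XERICO lost their calls without dark replicate 1 (adjusted p 0.0654 to 0.153), dark replicate 2 (0.0565 to 0.155), high light replicate 2 (0.0756 to 0.212) or high light replicate 3 (0.0825 to 0.185), and 1 or 2 of AT2G32030, AT4G36500, WRKY22 and XERICO without control replicate 1 (0.0714), 2 (0.0549 to 0.0746) or 3 (0.0543 to 0.0753) or dark replicate 3 (0.0550 to 0.0588). With only the 6 arrays of both groups, AT2G32030, WRKY22 and XERICO missed the threshold (0.0749 to 0.145), as WRKY22 did after quantile normalisation (0.0506).

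Besides the dark and sugar starvation, plastid and mitochondrial lists, which had 0 members called by limma in each comparison, 17 lists with 32 measured members, counted per list, had none that passed in any comparison. They were the heat shock, antioxidant, hydrogen peroxide, chlorophyll, carotenoid, flavonoid, light signalling, salicylate, ethylene, abscisate, protein folding, cell cycle, auxin, cell death, photorespiration, root and reference lists. Most genes of these lists had no named probe set. Measured were 2 of 22 heat shock, 3 of 20 antioxidant, 1 of 10 hydrogen peroxide, 1 of 16 salicylate and 1 of 15 ethylene genes. The absence of calls is therefore no result about these pathways as a whole. Lists that passed were thinly measured too, with 4 of 20 rapid stress, 3 of 9 calcium and touch and 4 of 12 singlet oxygen genes. For photosystem and Calvin cycle it was 9 of 34, and for dark and sugar starvation 4 of 20. Their calls likewise hold only for the measured members. Among the heat shock genes, the small heat shock protein gene AT2G29500 had a log2 change of -0.27 (SE 0.37) and AT5G48570 one of 0.02 (SE 0.23) in high light against control. Among the antioxidant genes, the glutathione reductase gene GR1 had -0.14 (SE 0.10) and the ascorbate peroxidase gene SAPX 0.08 (SE 0.25). At an unadjusted p under 0.05 in limma, 0 of the 32 were higher and 5 lower in high light against control, 1 higher and 1 lower in dark against control, and 2 higher and 1 lower in high light against dark.

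The responses to high light and to darkness were set side by side against the same control arrays. High light raised 94 probe sets against both control and dark, where independent lists would share 0.884 and 100 simulations of unchanged groups with shared high light arrays gave 0 to 1. The former leaves out the shared arrays and the latter the effects, and part of the overlap may come from the shared arrays. Of the calls, 96 were made in both comparisons of high light, 18 only against control and 108 only against dark. The log2 changes of high light and dark against control had a correlation of 0.134 across probe sets, which are not independent replicates. Unchanged groups simulated against these controls gave a mean correlation of 0.50 (0.460 to 0.542). High light was unchanged there too. Its real changes would lower the correlation even without an effect of darkness, so the observed and simulated correlations are not like for like. The covariance was 0.00706, below the simulated 0.0134 (0.0122 to 0.0153), a difference of -0.0064. The simulated arrays were drawn independently, whereas same-numbered arrays deviated together in most pairs (correlations from -0.0336 to 0.632), so these simulated values leave that structure out and the difference is not corrected for it. With the control arrays divided between both comparisons, the correlation ranged from -0.270 to 0.102. Each division gives the comparisons controls of different numbers, while dark and high light hold all numbers. Deviations shared by number then enter the changes with opposite signs and lower the correlation. These values are therefore not the correlation freed of the shared controls. It was -0.0484 with array weights, -0.0389 without dark replicate 3, 0.0427 without high light replicate 1, 0.299 without control replicate 2 and 0.222 without control replicate 3. Limma called 0 probe sets in both comparisons against control, as 0 were called in the dark, where 629 had an unadjusted p under 0.05.

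Over the 3 groups together, the moderated F test of limma called 144 probe sets. It called 494 with array weights, 349 with the replicate number as a block and 234 with an intensity trend and robust estimation. The count was 542 without high light replicate 1, 61 and 60 without high light replicate 2 or 3, 89 and 83 without dark replicate 1 or 2, and 94 without control replicate 3.

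High light replicate 1 showed less of the change than the other 2 high light arrays in the median over probe sets, though not for every gene. Without it, 395 probe sets were called higher and 180 lower against control, and 488 of these 575 (84.9%) lay on the same side of the control mean in replicate 1. The median share of the log2 change it showed was 0.321 (95% bootstrap interval 0.282 to 0.363), measured from the mean of all control arrays and not from control replicate 1. Among the named genes called with it in the fit, its share on the linear scale ran from 0.221 for AT2G32030 to 1.17 for AT4G27652. It was 1.05 for LHCB4.2, 0.972 for AT1G77640 and 0.946 for GI.

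**Figure D2:**
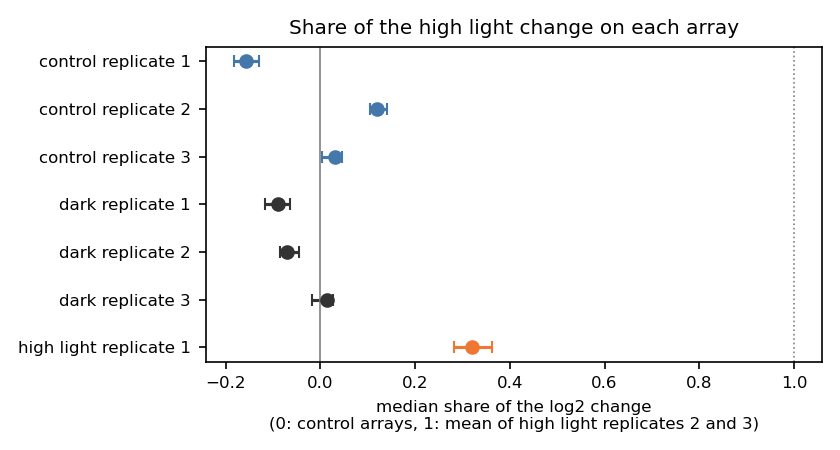
Median share of the log2 change of high light replicates 2 and 3 shown by each other array, over the 575 probe sets called without high light replicate 1, with 95% bootstrap intervals over probe sets. The control and dark arrays lie between -0.16 and 0.12, and high light replicate 1 at 0.32.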

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

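The RNA quality covariate and the lists by locus alone were chosen after the data were seen; the other settings were fixed beforehand. No called gene or list turned its direction, while the correlation of both responses, which has no test, changed sign under some settings. Of the calls of named genes, 550 of 626 combinations of gene and alternative kept the call and 76 lost it, and of the calls of lists 252 of 295 kept it and 43 lost it. Of those not called, 7 of 2223 combinations for genes and 19 of 518 for lists gained a call, among them 5 of 21 for GI in high light against dark (adjusted p 0.0249 to 0.259) and 11 of 23 for the singlet oxygen list in the dark, which lay lower there (0.0572 with the settings chosen, 0.00253 to 1 under the alternatives). Each array left out in turn gave 43 to 575 calls in high light against control, 0 in dark against control, 76 to 675 in high light against dark, 60 to 542 in the F test, a correlation of both responses from -0.0389 to 0.299, and 1 to 5 lists in the dark. Array weights gave 387, 5 and 642 calls in the 3 comparisons, 494 in the F test, a correlation of -0.0484 and 5 probe sets called in both comparisons against control; all 114 and 204 calls were among them. The arrays with the lowest weights were high light replicate 1 (0.481), control replicate 3 (0.507) and dark replicate 3 (0.555). An intensity trend with robust estimation gave 234 in the F test. Only the 6 arrays of both groups gave 131 calls in high light against dark. An adjusted p under 0.01 left 59 calls in high light against control and 84 against dark. Fewer calls there follow from the construction, and the cause of the other shifts was not tested. Control arrays divided between the comparisons gave correlations of -0.270, -0.219, -0.157, -0.117, 0.0832 and 0.102, which deviations shared by replicate number lower. With an estimated correlation 2, 0 and 3 lists were called in place of 5, 3 and 5. The directional fry test called 0 in the dark and 3 in high light against dark, the mixed one 0 in each comparison, neither being a test against other genes. The RNA quality covariate gave 5 lists in the dark, and a filter above the median mean gave 3 in high light against dark.

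The replicate number as a block gave 302 calls in high light against control, 113 of them shared with the 114, 430 in high light against dark, shared with all 204, 349 in the F test and 5 lists in the dark; dark against control stayed at 0 calls. The numbers met the criterion for pairing, a correlation over 0.1 in every pair, between high light and control and not in the other comparisons, with 7 of 9 pairs over 0.1 (-0.0336 to 0.632). As a hint from the data and not the design, 8 of 9 arrays correlated best with their own number. Signal over background was not analysed here, so changes of weakly expressed genes are the least certain.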

Other observations

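The tests of a mislabelled array, of 1 share for all genes, of RNA quality, of the shared control arrays and of 1 dark array were chosen after the results were seen; the members of the 22 family lists were set from the gene table before any fold change was computed, and the families and genes described here were picked after their values were seen. Among 9 measured genes of the PUB family of U-box ubiquitin ligases, 2 rose in high light against control, PUB22 and PUB23 (log2 change 2.30, SE 0.37, limma adjusted p = 0.0425, n = 3), and 3 rose against dark, PUB26 by 1.56 (SE 0.22, adjusted p = 0.0170) besides these. The family had camera adjusted p of 0.0040 and 0.00017, each lost with an estimated correlation (adjusted p = 0.596 and 0.343). PUB23 lost its call against control without any 1 array other than high light replicate 1 (adjusted p 0.0563 to 0.236), and against dark PUB23 or PUB26 or both lost it without dark replicate 1 (0.0642 to 0.0828), 2 (0.0547) or 3 (0.0565) or high light replicate 2 (0.0723) or 3 (0.0817 to 0.0924). Of 7 calmodulin-like genes, CML37 and CML23 rose in both, CML23 by 1.65 (SE 0.17, adjusted p = 0.0052) against control and 2.30 (SE 0.17, adjusted p = 0.00072) against dark. This family had camera adjusted p of 0.00016 and 2.4e-05, lost at 0.0791 and 0.0530 with an estimated correlation. The 27 wall-loosening genes, xyloglucan endotransglucosylases and expansins, had medians of 0.04 and 0.07 (camera adjusted p = 0.0235 and 0.0091, adjusted p = 0.596 and 0.331 with an estimated correlation), with 0 called by limma.

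In the dark, 47 measured glycosyltransferase genes had a median log2 change of -0.08 (camera adjusted p = 0.0213), 12 RNA polymerase subunit genes one of 0.15 (0.0273) and 10 plastid NDH genes one of -0.23 (0.0273); each had an adjusted p of 0.623 with an estimated correlation, and 0 members were called by limma. In high light against dark, 12 ubiquitin-conjugating enzyme genes had a median of -0.11 (camera adjusted p = 0.0355, adjusted p = 0.331 with an estimated correlation). No other family list passed in any comparison.

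High light replicate 1 lay nearer to the control arrays than high light replicates 2 and 3. The median share of the change it showed, 0.321 (0.282 to 0.363), lay above the intervals of all 6 control and dark arrays, the highest of which ended at 0.140. That argues against a mislabelled untreated array, by a criterion added when the share fell between the bounds of 0.25 and 0.5 first set. The 6 arrays were part of the fit that chose the probe sets and replicate 1 was not, so the shares are not on equal terms. The intervals cover probe sets and not the spread between arrays. The RNA quality index of replicate 1 differed from that of replicate 2 by 0.0311, less than replicates 2 and 3 differed, which argues against RNA quality. RNA of untreated cells in the sample stays open. The linear shares of risen and fallen probe sets, 0.230 and 0.315, differed by -0.0851 (-0.156 to -0.0167), within the 0.2 set beforehand though the interval excludes 0. Such a mixture needs 1 share for all genes, and the median linear share over the 575 probe sets was 0.261. AT1G77640 and AT4G27652 had linear shares of 0.972 and 1.17 where PUB22 had 0.225. These genes were called with replicate 1 in the fit, which favours genes that changed in it, so they do not decide the question. The spread around 1 share was a median absolute deviation of 0.37 on the log2 scale over all 575 probe sets. The 6 control and dark arrays had 0.34 to 0.48, each over the 61 to 131 probe sets called without that array. These sets differ, so the spreads are not like for like. Divided by the fitted SD of each probe set, the spread was 2.13, above the 1.16 to 1.86 of the 6 arrays. As an SD on the log2 scale it was 0.493, within the 0.361 to 1.23 of the 6 arrays. Dark replicate 3 had the highest of these, and the next was 0.461 on control replicate 2. Of 9 combinations of 3 selections and 3 measures that were tried, 5 put it above all 6 of these arrays, and 0 did so with an interval clear of theirs. A weaker or later response of that culture was not tested and stays open.

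Probe sets higher in high light lay lower in dark than in control: 78 of the 100 (78%) were below control, against 51.5% of all probe sets, with a median of -0.22. The medians of the 3 dark arrays were -0.28, -0.26 and -0.11, all below 0, which argues against a single dark array as the source. The spread between arrays may explain it, with an exact two-sided permutation p of 0.2 for the mean over these probe sets (n = 3 against 3, smallest possible 0.1). Simulated shared control arrays gave -0.10 to 0.08, and 0.04 to 0.11 with the probe sets chosen again, opposite in sign to the observed -0.22, which argues against them; they are not excluded by a criterion tightened after the median was seen, since the simulation draws each probe set independently and the control arrays lay at -0.27, 0.28 and -0.08 against each other. Without control replicate 2 the median was -0.13, and darkness as a biological cause stays untested.

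Other splits of the same arrays were tried for each count of calls. Of the 10 splits of the 6 arrays of high light and control, 1, the real one, gave as many as 114 calls, and the highest other gave 0, both among the 4 splits that part all 3 same-numbered pairs and among the other 6; for high light and dark, 1 of 10 gave as many as 204, and the highest other gave 0 among the 4 splits that part all 3 same-numbered pairs and 76 among the other 6. For dark and control, 10 of 10 gave at least the real 0, and the highest other gave 0, where limma had 629 probe sets at an unadjusted p under 0.05. In these comparisons 10 splits are too few for a share under 0.05. For the F test, 4 of 100 drawn regroupings, the real one included, gave at least the real 144, a share under 0.05 by a margin within the error of such a draw, so chance is not firmly excluded. The highest other, with 510, grouped the arrays by replicate number, which points to a structure of the samples. With the replicate number as a block the F test called 349. Another regrouping, with 233, kept all the high light arrays together, and the remaining one, with 194, kept the replicate 1 arrays together. Such regroupings hold part of the structure of the samples, so the share does not measure chance alone.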
